A study of Mus musculus with 48 samples.

How the data were processed

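The series measured liver RNA in C57BL/6J mice aged 15-16 weeks that were conventionally raised (convR) or germ-free (GF), in females and males fed ad libitum. Livers were taken at 6 zeitgeber times (ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22), with 2 libraries for each combination of sex, microbiome status and ZT. That makes 48 libraries in 4 groups of 12. Per the labels, libraries were made from total RNA after removal of ribosomal RNA and sequenced as paired reads. The labels number the libraries of a cell 1 and 2 but do not say that each came from a separate animal, so p-values measure the spread between samples. Duodenum, ileum and fat named in the shared extraction text were not analysed here.

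The authors deposited raw exon counts per gene, in a female table and a male table of 38087 genes each, together with an exon length per gene, a column in another unit that was not used. The submitters' processing notes give alignment with STAR 2.4.0i to mm10. The counting tool, the annotation, the handling of reads that match several genes and the handling of strand are not given in the sources used here. Values of close paralogs (the Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a12, Mup, Ugt, Sult2a, Gst, H2, Saa and Hist1 families) and of overlapping gene models such as Ctrc and Cela2a are therefore uncertain between members. Columns were joined to samples by the group, ZT and replicate number in their names. The male table's column names carry no sex, which was taken from the table. Counts of X-inactivation and Y-linked genes mismatched the labelled sex in 0 of 48 libraries. Coordinates are those of GRCm38 (mm10) in GENCODE M21, matched by identifier for 36308 genes.

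Total counts per library ran from 34335183 to 74892274 in convR males, 29769441 to 51294708 in GF males, 35575672 to 41536942 in convR females and 31637260 to 40973154 in GF females. The 10 most abundant genes held 17.2% ± 0.658 (SD, n = 12) of counts in convR males and 20% ± 2.11 in GF males. They held 18.7% ± 0.698 in convR females and 21.1% ± 2.13 in GF females. Levels are given in CPM of a library's total counts, as mean ± SD over 12 libraries. Where all libraries of a group held 0 counts of a gene, a fold was computed against a floor of 3 counts summed over that group and is a lower bound. With 1 to 3 counts the ratio carries a 95% exact counting interval. Intervals and floors cover counting error only.

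Genes were tested with the edgeR 4.0.16 quasi-likelihood F test (limma 3.58.1, R 4.3.3) after TMM scaling. Genes were kept by filterByExpr with a count minimum of 10 and a total minimum of 15, the cells of sex, status and ZT serving as groups. The means model held 1 coefficient per cell, and contrasts were averaged over the 6 ZT with equal weight. GF was compared with convR within each sex in 24 libraries. The interaction (GF minus convR in females, minus the same in males) and the sex difference within convR and within GF were fitted in all 48 libraries. Sex coincides with the table the counts came from. Rhythm was tested with a cosine and a sine term of 24 h period per group, and a change of rhythm between statuses or sexes by the interaction of those terms. Amplitudes are log2 half-ranges and peaks are given in ZT hours with delta-method SE. Log2 fold changes are given ± SE. Adjusted p-values are Benjamini-Hochberg values from edgeR over all genes tested, with a threshold of 0.05, unless another test is named.

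Fixed gene lists were core clock, bile acid synthesis, bile acid transport and signalling, targets of the xenobiotic receptors CAR and PXR, AhR targets, PPARα and fatty acid oxidation, lipogenesis, cholesterol synthesis, glucose metabolism, amino acid and urea metabolism, growth hormone and STAT5, male-biased genes, female-biased genes, sex chromosome check, interferon and antigen presentation, acute phase, stress chaperones and proliferation. Marker lists covered hepatocytes, Kupffer cells, B and plasma cells, T and NK cells, neutrophils and monocytes, sinusoidal endothelium, stellate cells, cholangiocytes, pancreas acinar cells, adipocytes, skeletal muscle and erythroid cells. Each list with at least 3 tested genes was compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over lists within a contrast. camera with an estimated correlation and fry were alternatives. fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

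Named genes follow a rule fixed with the lists. For each contrast of means it takes the 10 highest and the 10 lowest log2 fold changes among genes with adjusted p under 0.05, an average log2 CPM of at least 0 and the same direction at 5 or more of the 6 ZT. For each test of changed rhythm it takes the 10 genes with the lowest adjusted p and an average log2 CPM of at least 0. Predicted gene models and pseudogenes were counted but not named. Members of the fixed lists could also be named. Any other gene is said to have been chosen after its values were seen. Some genes that the rule or the lists take in are not reported here, though they count in the totals.

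For the sex axis, genes were called female- or male-biased (adjusted p under 0.05 and at least 2-fold) in convR libraries with replicate number 1 alone. The slope of the female minus male difference of these genes on their replicate 1 difference was then measured per ZT in convR libraries with number 2 and in GF libraries. A further slope took the GF mean of both numbers minus the convR library with number 2, within each sex, on the mean replicate 1 difference. Slopes over the 6 ZT were tested with a two-sided exact sign-flip permutation test, for which the smallest possible p is 0.0312.

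The method was tested on simulated counts with the real labels, depths and dispersions. Each gene had the same mean level in all libraries, apart from known changes planted in GF. In the GF contrast it recovered 94% of 67 genes changed 1.5-fold and 98.5% of 67 changed 2-fold in females, with 9 false calls among 204. In males the shares were 89.6% and 98.5%, with 15 false calls among 207. Changes of rhythm were recovered less well. They were planted as a rhythm gained in GF by genes without any, and shifts of an existing rhythm were not simulated. A 1.5-fold change was found for 4.48% of 67 genes in females and 8.96% in males, and a 2-fold change for 61.2% and 53.7%.

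Alternatives covered RLE size factors, library size as the only scaling, no filter, a stricter filter, robust dispersions, DESeq2 1.42.0, an adjusted p of 0.01, a replicate block, leaving out each library, ZT or replicate number, a harmonic model of means, a 5 df test of ZT, a peak-to-trough minimum of 1.5, and other choices for the axis. 7 libraries were singled out after the data were seen and left out as further alternatives. 3 GF female libraries held Nnt at over 2 times the median. 3 libraries held Ctrb1 above 20 CPM or Ckm above 5 CPM, pancreas and muscle genes. 1 GF male library gave over 2% of its counts to Mir5105. The axis without pseudogene and small RNA genes was also added after the data were seen. No library was left out of the values reported first. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.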

Results

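In both sexes GF livers held less Csad, Cyp3a11 and Top2a RNA and more Sult1e1 and Got1 RNA than convR livers, and the response of sex-biased, cholesterol-synthesis and acute-phase genes differed by sex. The comparisons below address how the microbiome, sex and time of day shape liver transcripts.

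In GF females, Csad, whose enzyme makes the taurine precursor hypotaurine, and Cyp3a11, a drug-metabolising cytochrome P450, fell at 6 of 6 ZT. Csad (ENSMUSG00000023044, chromosome 15, 102176999 to 102204724) went from 242 ± 142 CPM in convR to 22.6 ± 13.9 CPM in GF (SD, n = 12 libraries each), a log2 fold change of -3.23 ± 0.24 (edgeR adjusted p = 8.8e-07). Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964) went from 3050 ± 452 to 854 ± 216 CPM, a log2 fold change of -1.74 ± 0.09 (edgeR adjusted p = 9.73e-09). Sult1e1, the estrogen sulfotransferase (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), rose from 0.361 ± 0.218 to 23 ± 21 CPM, a log2 fold change of 6.02 ± 0.76 (edgeR adjusted p = 0.000198). 3 of the 12 GF female libraries (replicate 2 at ZT2, ZT6 and ZT10) held Sult1e1 at 0.632 to 1.79 CPM, against 9.66 to 63 CPM in the other 9. The same 3 libraries held Nnt, a mitochondrial transhydrogenase gene chosen after its values were seen, at 173 to 186 CPM against 44.4 to 75.5 CPM in the other 45 libraries.

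The other genes with the largest increases in GF females were Hapln1 (matrix link protein, log2 fold change 3.21), Serpina7 (thyroxine-binding globulin, 2.61), the imprinted RNA H19 (2.41), Gucy2c (guanylin receptor, 2.28), the metallothionein Mt2 (1.99), Igfbp1 (IGF-binding protein, 1.96) and Cyp3a44 (1.61). Ctrc and Cela2a, overlapping pancreatic protease genes, also rose (2.45), and 1 GF library (ZT22 replicate 1) held Cela2a at 69.2 CPM and the pancreas gene Ctrb1 at 57.4 CPM, with Cela2a at 6.53 CPM or less in the other GF female libraries. Without the libraries carrying pancreas or muscle counts the Cela2a log2 fold change was 1.52, and without replicate number 1 it was 0.44 and did not pass (adjusted p = 0.464). The largest decreases beside Csad and Cyp3a11 were in the histone gene Hist1h4m (-5.84), the sulfotransferase Sult2a3 (-2.45), the neurotrophin receptor Ntrk2 (-1.97), the sterol 12-alpha-hydroxylase Cyp8b1 (-1.67), Serinc2 (-1.58), the sulfatide-synthesis gene Gal3st1 (-1.53), the DNA-methylation maintenance gene Uhrf1 (-1.52) and the protease inhibitor Wfdc2 (-1.51). In all, 2417 of 16574 genes differed (edgeR quasi-likelihood, adjusted p under 0.05), 1161 higher and 1256 lower in GF. With all 7 singled-out libraries left out the count was 2109. It was 1476 without ZT2, 1374 without ZT10 and 1513 without ZT22. Igfbp1 no longer passed without ZT2 or ZT10 (adjusted p = 0.179 and 0.0562), nor with robust dispersions (adjusted p = 0.0559). Mt2 no longer passed without ZT10 or with the 7 singled-out libraries left out (adjusted p = 0.081 and 0.0709). Without replicate number 2, Igfbp1, Mt2 and Cyp3a44 did not pass (adjusted p = 0.196, 0.142 and 0.173), and without number 1 they did not either (0.186, 0.212 and 0.221). Hapln1 no longer passed without the GF library of ZT6 replicate 1 (2.61, adjusted p = 0.161). Without replicate number 1, which leaves 1 library per cell, 9 of the 20 named genes passed, Hapln1 measured 0.40 (adjusted p = 0.821) and Serpina7 measured 1.11 (adjusted p = 0.0497). Igfbp1 no longer passed without any 1 of 7 libraries, convR ZT10 replicate 1, ZT2, ZT6 and ZT14 replicate 2, and GF ZT10 and ZT18 replicate 1 and ZT2 replicate 2 (adjusted p = 0.0541, 0.0578, 0.0532, 0.0549, 0.0811, 0.06 and 0.0529). The Mt2 log2 fold change was 1.36 without GF ZT2 replicate 2, that of H19 1.79 and that of Uhrf1 -2.20 without GF ZT18 replicate 2. The split by direction depended on scaling. With library size as the only scaling, 4082 genes differed and 11.5% of them were higher in GF, against 48% with TMM, as the median log2 fold change of all genes moved to -0.12.

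Amino acid and urea-cycle genes rose in GF females, with 9 of 14 called higher and none lower. Got1, the cytosolic aspartate aminotransferase, rose by 0.94 ± 0.17 log2 and the urea-cycle genes Ass1 and Cps1 by 0.59 ± 0.10 and 0.52 ± 0.09. Proliferation genes fell, with 10 of 14 called lower, among them Top2a (-1.34 ± 0.27), Mki67 (-0.96 ± 0.22) and the replication helicase gene Mcm2 (-0.79 ± 0.18). Acute-phase genes were called higher in 7 of 17 cases, led by haptoglobin Hp (0.95 ± 0.16) and serum amyloid Saa1 (1.12 ± 0.23). Interferon and antigen-presentation genes were called lower in 8 of 24, among them Irf7 (-0.64 ± 0.09) and Oas2 (-0.57 ± 0.10). Lipogenesis genes were called lower in 7 of 16, among them Pnpla3 (-1.44 ± 0.40), the malic enzyme Me1 (-0.74 ± 0.16) and Scd1 (-0.75 ± 0.20). These lists passed camera with the preset correlation, the amino acid list with an adjusted p of 1.48e-08, as did hepatocyte markers (6 of 10 higher, Trf 0.37 ± 0.07), B and plasma cell markers (3 of 8 higher, Igkc 1.06 ± 0.22) and cholesterol synthesis (1 of 22 lower, and 0 when adjusted over the list alone). The mean level of hepatocyte markers was 12281 to 12512 CPM in the 3 GF female libraries with high Nnt, 15424 to 17794 CPM in the other 9 and 11759 to 14048 CPM in convR females.

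None of these 8 lists passed with an estimated correlation in females. For amino acid, proliferation, acute-phase, hepatocyte and B and plasma cell lists it gave adjusted p = 0.329 with an estimated correlation, while the lowest values over the 6 alternatives were 3.28e-16, 1.85e-08, 1.45e-07, 1.89e-07 and 7.57e-06. For interferon and lipogenesis genes it gave adjusted p = 0.625 with an estimated correlation (lowest 3.18e-05 and 8.61e-05), and for cholesterol synthesis adjusted p = 0.872 (lowest 1.39e-07). Adjusted over the list alone, 11 amino acid, 11 proliferation, 8 acute-phase, 9 interferon, 7 lipogenesis and 7 hepatocyte genes passed.

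In GF males, Cyp3a11 fell from 4261 ± 918 to 146 ± 60.1 CPM, a log2 fold change of -4.78 ± 0.18 (edgeR adjusted p = 1.59e-11), and Csad from 278 ± 71 to 26.4 ± 18.6 CPM (-3.37 ± 0.20). Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), a cytochrome P450 of female liver, rose from 0.0588 ± 0.0854 to 21.1 ± 20.9 CPM, a log2 fold change of 8.88 ± 0.83 (edgeR adjusted p = 1.06e-06). Cyp2a4 (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088), another female-biased P450, rose from 1.68 ± 1.11 to 22.4 ± 23 CPM (3.71 ± 0.47). Sult1e1 rose by 6.02 ± 0.52. Reads shared within the Cyp2a, Cyp2b and Cyp3a families leave the share of each member uncertain.

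The other genes with the largest increases in GF males were Fam19a2 (3.41), Lars2 (mitochondrial leucyl-tRNA synthetase, 3.23), the hepcidin gene Hamp2 (3.19), the phosphodiesterase Pde6c (3.05), the steroid hydroxylase Cyp17a1 (2.97) and Gpx6 (2.87). Lars2 ranged from 15.7 to 2851 CPM between GF male libraries, and the GF male library with its highest level (ZT6 replicate 2) gave 49425 CPM to the microRNA gene Mir5105, against 15297 CPM or less elsewhere. Mir5105 was chosen after its values were seen. It held 0.485% to 1.53% of counts in the other GF male libraries and 0.433% to 0.993% in convR male libraries. Without that library the Lars2 log2 fold change was 2.50, and without GF ZT2 replicate 2 it was 2.43. Lars2 no longer passed without replicate number 2 (2.29, adjusted p = 0.107). The largest decreases beside Cyp3a11 and Csad were in the major urinary protein genes Mup9 (-5.32), Mup17 (-4.77), Mup18 (-3.96) and Mup15 (-3.62), the carboxylesterase Ces2b (-4.09), Hist1h4m (-3.90), the glucuronosyltransferase Ugt2b38 (-3.73) and Saa2 (-3.65). In all, 4091 of 17550 genes differed (edgeR quasi-likelihood, adjusted p under 0.05), 1971 higher and 2120 lower in GF, and 4047 with the singled-out libraries left out. With library size as the only scaling 5877 differed, 16.9% of them higher against 48.2% with TMM, and the median log2 fold change of all genes was -0.12.

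**Figure D1:**
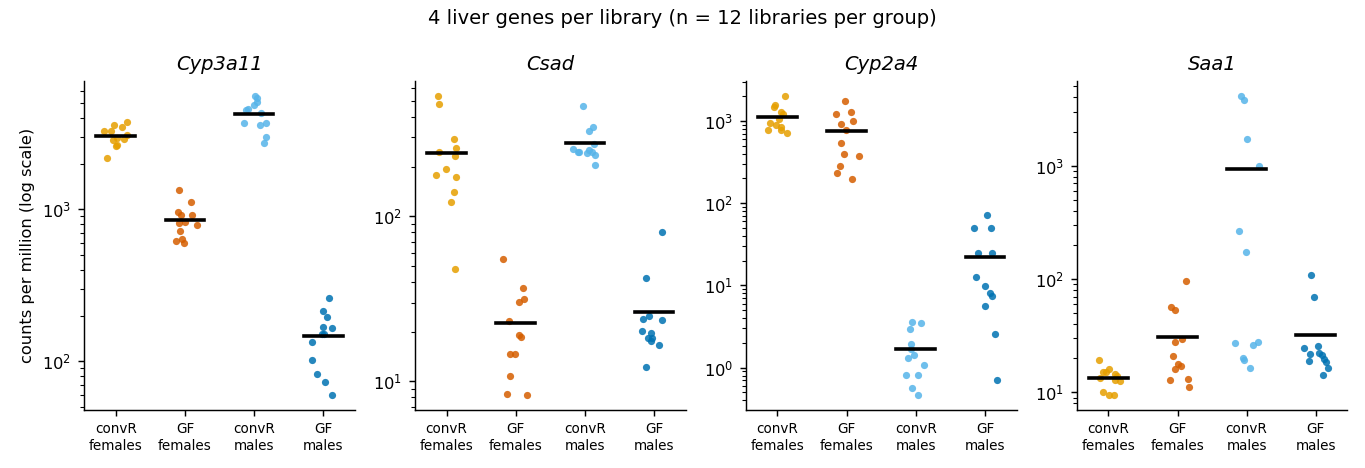
CPM (log axis) of Cyp3a11, Csad, Cyp2a4 and Saa1 in each library, 12 per group, with a bar at the group mean. GF means lie below convR means for Cyp3a11 and Csad in both sexes, though single libraries overlap for Csad in females, Cyp2a4 averages 1.68 CPM in convR males and 22.4 CPM in GF males, and Saa1 is spread over a wide range among convR males.

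Cholesterol-synthesis genes rose together in GF males. All 22 tested members were called higher, with a median log2 fold change of 1.06 (camera adjusted p = 5.2e-50, and adjusted p = 0.00969 with an estimated correlation). Hmgcs1, an early synthase of the pathway (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), rose from 286 ± 202 to 768 ± 385 CPM (1.66 ± 0.12), Idi1 by 1.46 ± 0.12 and Sqle by 1.35 ± 0.16. Amino acid and urea genes rose in 9 of 14 cases (Got1 1.47 ± 0.09, Ass1 0.81 ± 0.09, Cps1 0.63 ± 0.06, adjusted p = 0.0374 with an estimated correlation). Proliferation genes fell in 12 of 14 (Ccnb1 -1.95 ± 0.24, Top2a -1.36 ± 0.17, Mki67 -1.23 ± 0.14, adjusted p = 0.0426 with an estimated correlation).

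Genes of the male-biased list fell in GF males in 20 of 23 cases, with a median of -1.07 (adjusted p = 0.0267 with an estimated correlation). Gstp1, a glutathione transferase, fell from 1019 ± 168 to 309 ± 86.4 CPM (-1.61 ± 0.12), and so did the oxysterol hydroxylase Cyp7b1 (-1.44 ± 0.17), the carboxylesterase Ces4a (-2.69 ± 0.19) and the fatty acid hydroxylase Cyp4a12a (-1.41 ± 0.18). Genes of the female-biased list were called higher in 20 of 28 cases and lower in 3, with a median of 1.07, among them Cyp17a1 (2.97 ± 0.20) and the proton-pump subunit Atp6v0d2 (2.43 ± 0.24). Cyp3a16 (-5.12 ± 0.32) and Cyp3a41a (-4.34 ± 0.40) were among the 3 that fell. For this list the call was lost, with adjusted p = 0.235 with an estimated correlation and 1.47e-14 as the lowest of 5 alternatives. Of the growth hormone and STAT5 genes, Cish (1.57 ± 0.37), Cux2 (1.55 ± 0.41), Socs2 (0.83 ± 0.22) and Stat5b (0.28 ± 0.06) rose and Bcl6 fell (-1.06 ± 0.25), and the list of 12 as a whole did not pass (camera adjusted p = 0.245).

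Acute-phase genes were called lower in 7 of 17 cases in GF males and higher in 1 (Orm3, 0.71 ± 0.21). Saa1 (-2.64 ± 0.39) and the heme-binding protein Hpx (-0.35 ± 0.05) fell. Among convR male libraries Saa1 reached 3821 and 4118 CPM at ZT22 and 991 and 1705 CPM at ZT6, against 16.3 to 265 CPM at the other 4 ZT. Xenobiotic receptor targets moved both ways, with 9 of 24 higher and 9 lower. Cyp2b10 (-2.52 ± 0.32) and Ces2a (-1.23 ± 0.06) fell while Cyp2c54 (1.14 ± 0.14) and Cyp2c50 (0.78 ± 0.10) rose. That list's median was 0.09, its mean -0.36 and its camera direction lower. PPARα and fatty acid oxidation genes were called higher in 10 of 25 and lower in 2, among them the thioesterase Acot3 (2.61 ± 0.41) and Cyp4a14 (1.80 ± 0.32). Lipogenesis genes were called higher in 5 of 16, among them the desaturases Fads2 (0.83 ± 0.07) and Fads1 (0.69 ± 0.09). Glucose genes were called higher in 5 of 14 (Igfbp1 2.52 ± 0.39, Gys2 0.76 ± 0.08) and bile acid transport genes in 6 of 15 with 1 lower (Slco1a4 1.18 ± 0.17, Klb 0.68 ± 0.07).

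Markers of other cells moved with these groups. Kupffer cell markers were called lower in 6 of 13 cases in GF males (Folr2 -0.40 ± 0.08, Clec4f -0.27 ± 0.08), and their mean level was 38.4 ± 8.36 CPM in convR and 29.3 ± 4.78 CPM in GF. B and plasma cell markers were called higher in 3 of 8 (Ighm 1.06 ± 0.24), and hepatocyte markers in 5 of 10 (Ahsg 0.59 ± 0.06, Alb 0.61 ± 0.07). All of these lists, and the acute-phase, xenobiotic, PPARα, lipogenesis, glucose and bile acid transport lists, passed camera with the preset correlation. With an estimated correlation they did not. It gave adjusted p = 0.389 for acute-phase, xenobiotic, lipogenesis, Kupffer, B and plasma cell and bile acid transport lists (lowest of 5 alternatives 0.000578, 0.00499, 6.97e-05, 0.000149, 0.00434 and 0.000418), 0.581 for PPARα (lowest 0.00121), 0.356 for glucose and 0.0501 for hepatocyte markers. Adjusted over the list alone, 19 xenobiotic, 14 PPARα, 11 amino acid, 9 acute-phase, 9 Kupffer, 12 proliferation, 22 male-biased and 24 female-biased genes passed in GF males.

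Neither the bile acid synthesis list (camera adjusted p = 0.586 in females and 0.611 in males) nor the AhR target list (0.789 and 0.192) passed in either sex, though single members did. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), fell in GF females from 428 ± 226 to 211 ± 148 CPM (-1.17 ± 0.21) and measured -0.24 in males, where it did not pass. The effect differed between the sexes by -0.94 ± 0.29 (edgeR interaction, adjusted p = 0.0441). Cyp7b1 fell in males and measured 0.06 in females (edgeR interaction, adjusted p = 0.00194). Neutrophil markers S100a8 and S100a9 fell in GF males (-1.35 ± 0.25 and -1.09 ± 0.27), and S100a9 in females (-1.05 ± 0.18), while their list did not pass (camera adjusted p = 0.168 and 0.226). Of the stress chaperones, Hspa1b fell in both sexes (-0.83 ± 0.19 and -1.04 ± 0.21), and the list missed the threshold (camera adjusted p = 0.586 and 0.0827).

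The lists of core clock (camera adjusted p = 0.406 in females and 0.226 in males), T and NK cell (0.542 and 0.383), sinusoidal endothelium (0.663 and 0.611), stellate (0.858 and 0.611), cholangiocyte (0.698 and 0.35), adipocyte (0.663 and 0.898) and erythroid (0.586 and 0.969) genes did not pass for the GF effect in either sex. In females the male-biased (0.342), female-biased (0.663), growth hormone (0.556), xenobiotic (0.729), PPARα (0.279), glucose (0.418), bile acid transport (0.437) and Kupffer (0.858) lists did not pass, and in males the interferon list (0.0938) did not. Per3 fell (-0.98 ± 0.12) and Npas2 rose (1.06 ± 0.18) in mean level in GF females. Pancreas and skeletal muscle lists held under 3 tested genes in the single-sex fits. For pancreas genes no sex difference passed in convR, where the median was -4.57, or -4.78 with genes at 0 set to their bound (camera adjusted p = 0.192).

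The GF effects overlapped between the sexes. Of 16322 genes tested in both, 432 were called higher in both, against 137 under independence (Fisher's exact p = 3e-122), and 495 lower in both, against 156 (Fisher's exact p = 5.42e-145). 94 were called in opposite directions. The log2 fold changes correlated across genes at Pearson r = 0.448, and genes are not independent replicates. Got1, Top2a, Irf7, Csad, Cyp3a11 and Sult1e1 were among those called the same way in both.

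The GF effect differed between the sexes for 1443 of 17867 genes (edgeR interaction, adjusted p under 0.05), 664 with a higher and 779 with a lower effect in females. Cyp3a11 fell less in females, with a difference of 3.04 ± 0.19 log2 (adjusted p = 1.13e-11). Cyp2b9 stood at 459 ± 58.5 CPM in convR and 405 ± 83.2 CPM in GF females, and its effect differed from that in males by -8.94 ± 0.76. The other genes with a higher effect in females were Cyp3a41a (4.68), Mup17 (4.32), the serum amyloids Saa2 (4.07), Saa1 (3.75) and Saa3 (2.98), Mup18 (3.12), Cyp3a44 (3.09), the ER-degradation gene Derl3 (2.98) and Ugt2b38 (2.87). Those with a lower effect were Cyp2a4 (-4.39), Hamp2 (-3.22), Fam19a2 (-3.11), the acetylcholine receptor gene Chrna4 (-2.97), Acot3 (-2.90), Atp6v0d2 (-2.83), the transcription factor Nfe2 (-2.69) and the transporter Slc22a26 (-2.67). The count was 603 without ZT10, 791 without ZT18 and 778 without the 3 libraries carrying pancreas or muscle counts, while 1513 passed with all 7 singled-out libraries left out. Mup17 and Mup18 no longer passed without the 3 GF female libraries with high Nnt (2.64 and 2.69, adjusted p = 0.496 and 0.212), nor did Derl3 (0.0609). Cyp3a44 no longer passed without the libraries carrying pancreas or muscle counts (adjusted p = 0.0797). Without replicate number 1 or 2, 8 and 13 of the 20 genes taken by the rule passed. Cyp3a41a no longer passed without ZT18, Cyp3a44 without ZT14 or ZT18, Derl3 without ZT10 or ZT18 and Chrna4 without ZT6 or ZT10 (adjusted p = 0.0525, 0.0895, 0.0732, 0.0736, 0.0953, 0.0555 and 0.0896). Leaving out single libraries, Mup17 was lost without female GF ZT6 replicate 2 (adjusted p = 0.447), Mup18 without female GF ZT2, ZT6 or ZT18 replicate 2 (0.157, 0.144 and 0.0729) and Derl3 without female GF ZT14 replicate 1 (0.0512). Cyp3a44 was lost without male convR replicate 1 at ZT2, ZT14, ZT18 or ZT22 (0.0611, 0.0623, 0.0515 and 0.104).

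**Figure D2:**
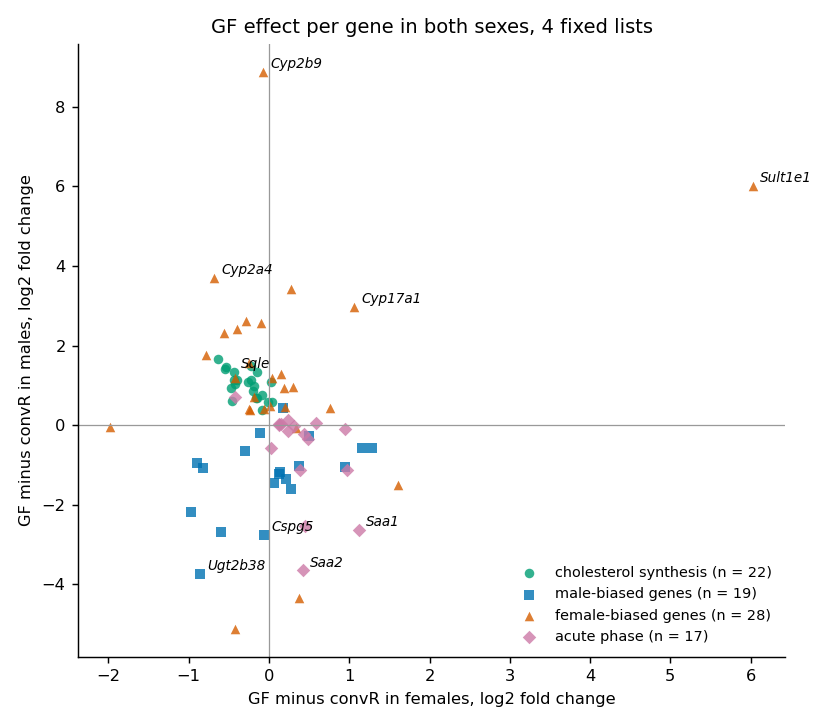
GF minus convR log2 fold change of each gene in females (horizontal axis) and males (vertical axis) for cholesterol-synthesis, male-biased, female-biased and acute-phase genes tested in both sexes. All 22 cholesterol-synthesis genes lie above 0 on the male axis, and Cyp2b9 lies highest, at 8.88.

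By list, all 22 cholesterol-synthesis genes had a lower GF effect in females than in males, with a median of -1.35 and Hmgcs1 at -2.30 ± 0.31. Acute-phase genes had a higher effect in females in 10 of 17 cases and a lower one in 1 (median 0.61, Hp 1.05 ± 0.18), male-biased genes a higher effect in 12 of 23 (median 1.40, Gstp1 1.88 ± 0.15), and female-biased genes a lower effect in 18 of 33 and a higher one in 2 (median -0.90, Cyp17a1 -1.91 ± 0.28). These 4 lists passed camera, with adjusted p = 0.00917, 0.00917, 0.00917 and 0.0425 with an estimated correlation. The acute-phase difference includes the convR male libraries at ZT22 and ZT6, in which Saa1 was high. Lipogenesis genes had a lower effect in females in 8 of 16 (median -0.83, Scd1 -1.13 ± 0.27), PPARα genes in 7 of 25 (median -0.19, Acot2 -1.15 ± 0.20), and xenobiotic targets a higher one in 4 of 24 and a lower one in 1 (median 0.17). The Kupffer list shifted with 0 of 13 members called (median 0.30). These passed with the preset correlation alone, with adjusted p = 0.143, 0.385, 0.562 and 0.539 with an estimated correlation, and lowest values of 2.41e-11, 8.62e-14, 0.0287 and 0.000112 over 6 alternatives. For amino acid genes (camera adjusted p = 0.92), proliferation genes (0.92) and interferon genes (0.214) no difference between the sexes passed.

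Females and males differed in 9058 of 17867 genes in convR livers (edgeR, adjusted p under 0.05), 4673 higher in females and 4385 higher in males. Leaving the X-inactivation gene Xist aside, highest in convR females were the sulfotransferases Sult2a1 (288 ± 105 against 0.0106 ± 0.0172 CPM), Sult2a2 (log2 difference 14.27), Sult3a1, Sult2a3 and Sult2a5. Cyp2b9 (13.57), A1bg (11.52) and Cyp2a4 (9.62) were also among them. Sult2a5 held 5373 counts in females and 0 in males, at least 1944-fold higher. Sult3a1 held 36488 against 3 counts, a ratio of 13202 (exact 95% interval 4517 to 64023). Leaving Y-linked genes aside, highest in convR males were Cyp4a12a (147 ± 19.7 against 0.0351 ± 0.0442 CPM), Cyp4a12b (log2 difference -10.86), Mup7 (-11.17) and Mup1 (-9.75). The steroid dehydrogenase Hsd3b5 (-9.08) and the intestinal sucrase-isomaltase Sis followed, with Sis at 1314 counts against 0, at least 404-fold higher. Of the fixed lists, 23 of 23 male-biased genes were higher in males and 32 of 33 female-biased genes in females. Interferon genes (21 of 24), cholesterol synthesis (21 of 22), lipogenesis (13 of 16), Kupffer (11 of 13), T and NK cell (11 of 12), sinusoidal endothelium (8 of 9), stellate (7 of 9), PPARα (15 of 25) and growth hormone (8 of 12) genes were mostly higher in females. Of 24 xenobiotic genes 12 were higher and 5 lower in females. The sex chromosome check genes followed the labels, 1 higher in females and 4 in males, with a median of -12.64, or -11.9 at the bound. Of these, the male-biased, female-biased and sex chromosome lists passed with an estimated correlation and the others did not (adjusted p = 0.112 to 0.456 with an estimated correlation).

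The sex difference persisted in GF livers, with 7589 genes called (edgeR, adjusted p under 0.05), 3775 higher in females and 3814 in males. Leaving Xist aside, highest in GF females was Sult2a1, with 78298 counts against 3 in males (ratio 28880, exact 95% interval 9882 to 140050). Cyp3a41a (14.26), Sult2a2 (13.11), Cyp3a16 (11.60), Cyp3a44 (11.34), Cyp3a41b, Sult2a5, Sult3a1 (10.34) and Sult2a3 followed. Leaving Y-linked genes aside, highest in GF males were Cyp4a12b (-11.40), Cyp4a12a (-10.19) and Mup7 (-9.80). Sis (-8.57), Mup1 (-7.82) and the acetyltransferase gene Cml5 (-7.54) followed. 33 of 33 female-biased list genes were higher in females and 22 of 23 male-biased genes in males. Xenobiotic genes were higher in females in 13 of 24 cases and lower in 1, and this list passed with an estimated correlation as well (camera adjusted p = 3.22e-12, and adjusted p = 0.0207 with an estimated correlation). Kupffer (12 of 13), interferon (18 of 24), T and NK cell (10 of 12), sinusoidal endothelium (6 of 9), stellate (6 of 9) and PPARα (9 of 25, with 2 lower) genes were called higher in females, and bile acid synthesis (6 of 13) and erythroid (1 of 6) genes lower. These passed with the preset correlation alone, with adjusted p = 0.209, 0.334, 0.33, 0.209, 0.253, 0.563, 0.253 and 0.536 with an estimated correlation. Cholesterol-synthesis genes were lower in females in 16 of 22 cases (median -0.59), the opposite of convR (median 0.59, interaction above), with adjusted p = 0.549 with an estimated correlation in GF, 0.456 in convR and the lowest alternatives at 1.26e-08 and 5.81e-07. Acute-phase genes were higher in GF females in 8 of 17 (median 0.38, camera adjusted p = 0.0176, adjusted p = 0.438 with an estimated correlation). Adipocyte markers were higher in males in 5 of 5 cases in convR and in GF, at 0.896 ± 0.593 against 0.0956 ± 0.121 CPM in convR and 0.948 ± 0.971 against 0.41 ± 0.571 CPM in GF, and their list did not pass (camera adjusted p = 0.0519 and 0.13).

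Along the sex difference as a whole, GF livers kept most of it. Of 1359 genes biased at least 2-fold in convR libraries of replicate number 1, 321 were female-biased and 1038 male-biased. In the convR libraries of number 2 the slope of their female minus male difference was 0.914 ± 0.037 (SD over 6 ZT), and in GF libraries 0.75 ± 0.0653 with the same number and 0.79 ± 0.0816 with the other. GF was lower by a mean of -0.164 (exact sign-flip permutation p = 0.0312, the smallest possible, lower at 6 of 6 ZT). In GF males the slope of the change was 0.0982 ± 0.06 toward female levels (exact p = 0.0312, above 0 at 6 of 6 ZT). Of the female-biased genes 226 of 321 were higher in GF males, with a median change of 0.30 log2, while 577 of 1038 male-biased genes were lower, with a median of -0.04. The 23 genes of the fixed male-biased list fell more, by a median of -1.07. In females the slope was -0.0455 ± 0.0442 (exact p = 0.0625, n = 6), and the sexes differed by -0.144 ± 0.0405 (exact p = 0.0312, n = 6). By construction this difference equals the mean slope in GF libraries of both numbers minus the convR slope. It restates the loss above and is not a separate result. Many male-biased genes were pseudogenes or small RNAs, whose counts may differ between the female and male tables. Without such genes, a choice made after the data were seen, 785 genes remained. Their mean slopes were 0.902 in convR and 0.728 in GF libraries with the same number (a loss of -0.173, exact p = 0.0312, n = 6). Of the female-biased genes left, 220 of 312 were higher in GF males (median 0.29 log2). Of the male-biased genes left, 245 of 473 were lower (median -0.018). The slope of the change was then 0.115 in GF males (exact p = 0.0312, n = 6) and -0.0475 in GF females (exact p = 0.0625, n = 6).

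**Figure D3:**
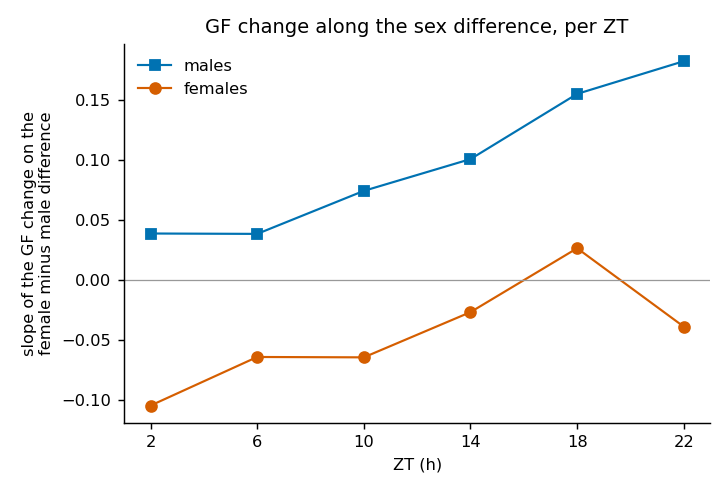
Slope of the GF minus convR change on the female minus male difference over 1359 sex-biased genes, at each ZT in males and females. The male slopes lie between 0.0384 and 0.182 and the female slopes between -0.105 and 0.0264.

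Core clock genes cycled in all 4 groups. 17 of 19 passed the rhythm test in convR females, 16 in GF females, and 17 in both male groups (edgeR, 2 df, adjusted p under 0.05). In GF females the fitted peaks lay later for 17 of 19 genes, with a median shift of 1.92 h. Per3 peaked at 11.6 ± 0.55 h in convR and 14.8 ± 0.45 h in GF, and the output factor Dbp at 10.2 ± 0.42 h and 12.8 ± 0.43 h. In GF males 3 of 19 peaked later and the median shift was -1.34 h, from -1.77 to -0.47 h over the alternatives. Arntl (Bmal1) peaked at 23.2 ± 0.75 h in convR and 21.3 ± 0.46 h in GF. Amplitudes were larger in GF males for 16 of 19 genes (median difference 0.50 log2, Nr1d1 from 1.91 ± 0.22 to 3.09 ± 0.24) and in GF females for 12 of 19 (median 0.14, from -0.09 to 0.26 over the alternatives, so without a stable sign). Adjusted over the list alone, 13 genes changed rhythm in females, among them Npas2, Per2 and Bhlhe40, and 7 in males, among them Dbp, Cry1 and Nr1d1, while 0 did so over all genes in either sex. Peak SEs were 1.54 h or less for every gene but Rora, which did not pass the rhythm test in any group.

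**Figure D4:**
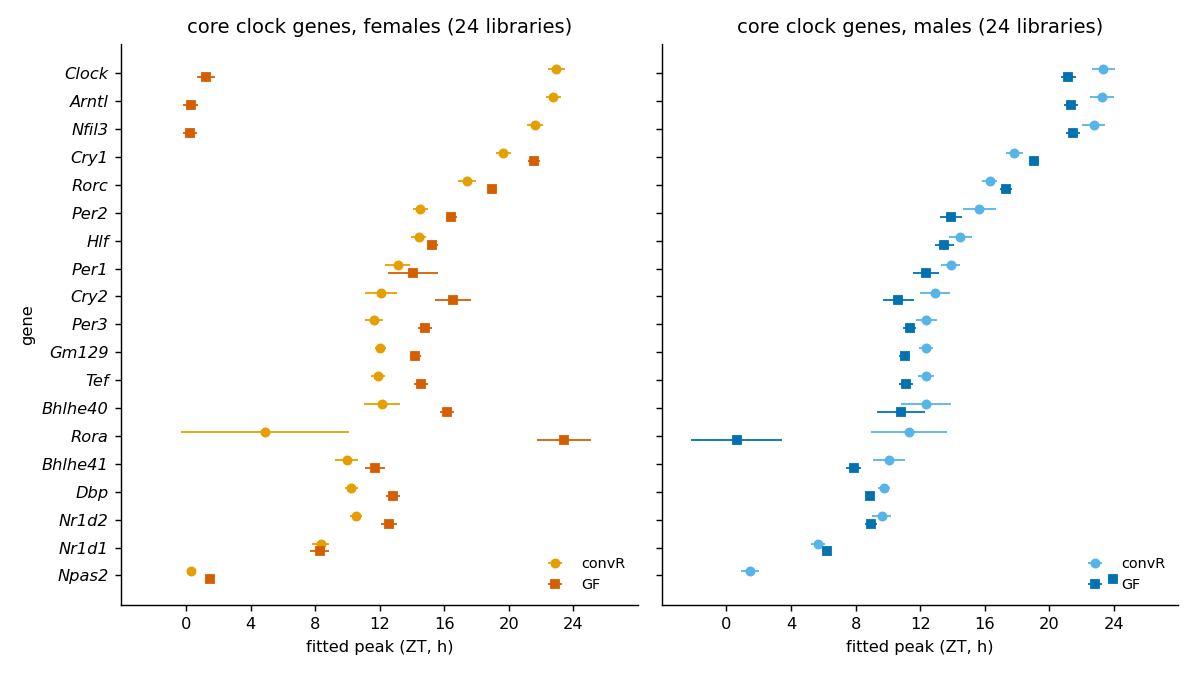
Fitted peak time (ZT, h) of 19 core clock genes in convR and GF livers of females and males, with bars of 1 SE from 24 libraries per sex. GF peaks lie later than convR for 17 genes in females and for 3 in males.

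In females 1967 genes were rhythmic in convR and 2041 in GF, 878 of them in both, against 242 under independence (edgeR, adjusted p under 0.05). Their peaks lay a median of 1.54 h later in GF, and 59.7% were within 2 h. No gene changed rhythm over all genes (edgeR interaction, lowest adjusted p = 0.0547, for the adenylate kinase Ak4), while 1940 had an unadjusted p under 0.05 and DESeq2 called 278. Ak4 peaked at 12.5 h in convR and 16.6 h in GF, and Slc25a37, Tmem57, Rbm47, Pcsk4, Npas2, Kif3b, Itsn1, Fnip2 and Rprd1a came next (adjusted p = 0.0875 each). Lipogenesis genes were rhythmic in 1 of 16 cases in convR and 11 in GF, and 14 changed when adjusted over the list alone. Thrsp, a lipogenic regulator, had an amplitude of 0.67 log2 in convR and 2.79 in GF with a GF peak at 18 h. The 3 GF libraries with high Nnt lay at the consecutive times ZT2, ZT6 and ZT10. What sets them apart can therefore enter the GF rhythm terms, and these lipogenesis values include them. The convR count fell to 1210 without ZT2, 898 without ZT10, 1194 without ZT14 and 966 without ZT22, to 1214 without ZT10 replicate 2 and to 1288 without ZT14 replicate 2. The GF count was 939 without ZT14, 1137 without ZT22 and 1272 with the singled-out libraries left out. The number of changed genes was 62 without ZT18, 5 without ZT2, 3 without ZT10 and 3 without ZT14. It was 227, 25, 20, 4, 3 and 2 without the GF libraries of ZT18 replicate 1, ZT2 replicate 1, ZT18 replicate 2, ZT2 replicate 2, ZT14 replicate 2 and ZT22 replicate 2, and 1 without either convR library of ZT6.

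In males 1540 genes were rhythmic in convR and 2955 in GF, 839 in both, against 259 under independence. Their median peak shift was -0.77 h, and 67.1% were within 2 h. 22 genes changed rhythm (edgeR interaction, adjusted p under 0.05), led by the linker histone Hist1h1d (peak 20.9 h in convR and 6.26 h in GF, adjusted p = 0.00426), Ahctf1, Ikbkg, Crybg3, Hist1h1e, Ric8, the glutathione-synthesis gene Gclc, Ugdh, Hist1h4f and Cyp7a1. Cyp7a1 had an amplitude of 0.19 log2 in convR and 2.07 in GF, with a GF peak at 14.4 h (adjusted p = 0.023). Cholesterol-synthesis genes were rhythmic in 14 of 22 cases in convR and 12 in GF, and 18 changed when adjusted over the list alone, against 0 over all genes. Lipogenesis genes were rhythmic in 3 of 16 in convR and 9 in GF (8 changed over the list alone). Acute-phase genes were rhythmic in 12 of 17 in convR and 0 in GF, with 0 changed when adjusted over the list alone and 9 at an unadjusted p under 0.05. These counts rested on few samples, and chance could not be excluded for the 22. Of 100 splits of the samples 5 gave as many, but splits that move GF labels can carry mean GF effects into the rhythm terms. The convR count was 377 without ZT10, 453 without ZT14, 931 without ZT18, 2754 without ZT2, 2601 without ZT22, 599 without the 3 libraries carrying pancreas or muscle counts and 2410 without the GF library of ZT6 replicate 2. It was 1019, 878 and 890 without the convR libraries of ZT10 replicate 1, ZT14 replicate 1 and ZT10 replicate 2. The GF count was 1522 without ZT10, 1460 without ZT14 and 1864 without ZT18. The number of changed genes was 0 without ZT18, 2 without ZT10, 5 without ZT14, 14 without ZT6, 44 without ZT22, 194 without ZT2 and 4 with the singled-out libraries left out. Single libraries left out gave 13, 10, 11, 14, 8 and 11 for convR ZT18 and ZT22 replicate 1 and ZT6, ZT10, ZT18 and ZT22 replicate 2, and 13, 5 and 35 for GF ZT18 replicates 1 and 2 and ZT22 replicate 2.

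Rhythms differed between the sexes for 0 genes in convR (edgeR, lowest adjusted p = 0.188, for Nrip1, with 651 at an unadjusted p under 0.05 and 4 by DESeq2) and for 58 in GF. The 58 included the clock genes Dbp and Nr1d2, the membrane protein gene Susd4, the transcription factor Klf10, Pcsk4, the pyridoxal kinase Pdxk, Rnf39, the cell-cycle inhibitor Cdkn1a, Ak4, the glycogen synthase Gys2 and Lrp4. Dbp peaked at 12.8 ± 0.43 h in GF females and 8.91 ± 0.25 h in GF males (adjusted p = 0.00478). Chance could not be excluded for the 58. Of 60 splits of the samples 4 gave as many, but splits that move sex labels can carry mean sex differences into the rhythm terms. The GF count was 3 without the 3 GF female libraries with high Nnt, 2 without ZT6, 11 without ZT14, 21 without ZT22 and 130 without ZT2, and 0 with all 7 singled-out libraries left out. Single libraries left out gave 37, 33, 21, 36 and 32 for male ZT6 and ZT18 replicate 1 and ZT6, ZT14 and ZT18 replicate 2, and 30, 15, 34 and 132 for female ZT6 replicate 1 and ZT6, ZT10 and ZT18 replicate 2.

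Some genes set single libraries or whole colonies apart, and these were chosen after their values were seen. The 3 GF female libraries with high Nnt held the endosomal gene Wdfy1 (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143) at 34.3 to 39.6 CPM, against 5.93 to 11 CPM in the other 45. Nnt lies on chromosome 13 (ENSMUSG00000025453, 119335448 to 119408997). Ide, the insulin-degrading enzyme (ENSMUSG00000056999, chromosome 19, 37268743 to 37337852), was lower in every GF library than in every convR library of the same sex, with log2 fold changes of -0.73 ± 0.10 in females and -0.98 ± 0.09 in males (edgeR adjusted p = 0.000336 and 4.41e-07).

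**Figure D5:**
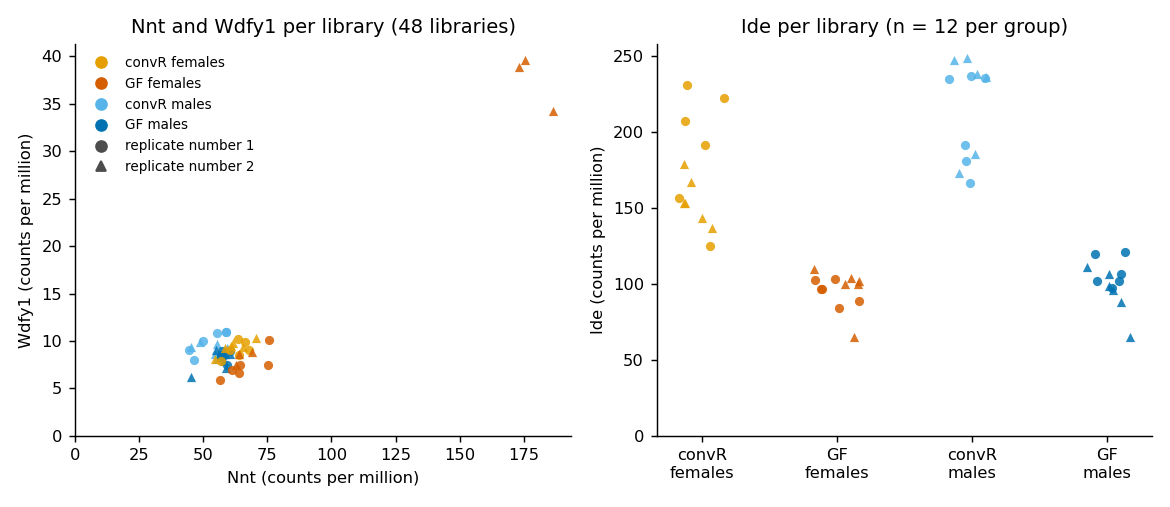
CPM of Nnt against Wdfy1 in 48 libraries, and CPM of Ide in each library by group. 3 GF female libraries lie apart at 173 to 186 CPM of Nnt, and the lowest convR library of each sex lies above the highest GF library at Ide, by a ratio of 1.14 or more.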

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

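The tests of the shift of GF males along the sex difference, of the libraries with high Nnt and of Ide, and the test of pseudogenes, were chosen only after the result was seen. The tests of depth, of intestinal genes and of other splits of the samples were not.

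The effect of GF status differed between the sexes by an interaction test. It did so for 1443 genes (edgeR, adjusted p under 0.05), and the highest other of 50 splits gave 795. These splits moved GF labels within sex and ZT, which also removed the GF effect common to both sexes. They therefore cannot decide whether chance made the difference between the sexes. By gene the differences, females minus males, were 4.68 for Cyp3a41a, 4.32 for Mup17, 4.07 for Saa2, 3.75 for Saa1, 3.12 for Mup18, 3.09 for Cyp3a44, 3.04 for Cyp3a11, 2.98 for Derl3, 2.98 for Saa3 and 2.87 for Ugt2b38. They were -8.94 for Cyp2b9, -4.39 for Cyp2a4, -3.22 for Hamp2, -3.11 for Fam19a2, -2.97 for Chrna4, -2.90 for Acot3, -2.83 for Atp6v0d2, -2.69 for Nfe2 and -2.67 for Slc22a26. By list the median differences were 0.17 for xenobiotic targets, -0.19 for PPARα, -0.83 for lipogenesis, -1.35 for cholesterol synthesis, 1.40 for male-biased, -0.90 for female-biased, 0.61 for acute-phase and 0.30 for Kupffer genes. The xenobiotic, PPARα, lipogenesis and Kupffer lists lost the call with an estimated correlation (adjusted p = 0.562, 0.385, 0.143 and 0.539), and 0 of 13 Kupffer genes were called.

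GF males moved toward female levels along the sex difference, and the sexes differed in that slope by -0.144. By construction that difference restates the loss of the sex difference in GF and is not a separate result. The median change was 0.30 log2 for female-biased and -0.04 for male-biased genes, so the typical male-biased gene of this choice hardly moved. Many of these were pseudogenes or small RNAs, and the median was -0.018 for the 473 male-biased genes left without them. The 23 genes of the fixed male-biased list fell by a median of -1.07. Female RNA or swapped labels in the GF male libraries were argued against, because Xist in GF males stood at 0.00984% of its GF female mean while Cyp2b9 stood at 5.21%. A few outlying GF male libraries were argued against too, since the lowest slope of any single ZT was 0.0384. A response of the male liver to the missing microbiome remains a hypothesis, and may include other differences between the colonies, which the design cannot separate from GF status.

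Nnt, Wdfy1 and Ide followed single libraries or colonies. 25 genes separated the 3 GF female libraries with high Nnt from all other female libraries, against at most 7 for any other 3 GF female libraries. Of the 24 with a known position 15 lay on chromosome 13, and 10000 random gene sets gave a 95th percentile of 5. The 15 include Nnt, by which the libraries were picked. Prl2c5, SNORA73 and a 7SK gene among them had the same log2 difference of 2.85. The 15 are thus not all independent, which random sets of single genes do not reproduce. A strain variant in those 3 libraries is therefore a candidate explanation. The other GF female libraries with replicate number 2 held Nnt at 69.1 CPM or less, so the high level did not follow that number as a whole. As the 3 libraries were picked by their Nnt level, this cannot decide on a library batch of those 3 alone. For Ide, the lowest convR library stood 1.14 times above the highest GF library in the sex with the smaller gap, but a variant between the colonies and an effect of GF status cannot be told apart, because genes within 200 kb were mixed. As shares of the convR level in females and males, Kif11 stood at 0.61 and 0.58 and a pseudogene inside Ide at 0.665 and 0.558. Hhex stood at 0.813 and 1.22, Cpeb3 at 0.876 and 0.98 and March5 at 0.943 and 0.978. Fgfbp3, which lies further off on the same chromosome (36917550 to 36919615), stood at 0.389 and 0.509.

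Low-abundance genes were mostly higher in males. Of genes differing at least 2-fold in convR, 1752 were higher in males and 453 in females, and 1305 and 195 of these had an average log2 CPM under 0. Different depth was argued against, since thinning every library to the lowest total left a ratio of 3.62. RNA of other tissues in the male libraries could contribute, as 9 of 10 tested intestinal genes were higher in convR males, among them Zg16, Alpi and Mep1b. Counts on pseudogenes and small RNA repeats that differ between the female and male tables could contribute as well, as such genes made up 55.7% of the genes at least 2-fold higher in males and 12.3% of all tested genes, and a biological sex difference stayed untested.

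Rhythms differed between the sexes in GF for 58 genes by the interaction of the rhythm terms, and chance could not be excluded. Of 60 splits 4 gave as many, and the highest other split gave 2734. These splits moved sex labels within status and ZT, so mean differences between the sexes could enter the rhythm terms. They therefore cannot decide whether chance made the 58. For the 22 genes with changed rhythm in males chance could not be excluded either. Of 100 splits 5 gave as many, and the highest other gave 1272. Those splits moved GF labels within ZT, so mean GF effects could enter the rhythm terms, and they cannot decide either. For the counts of 0 in females and between the sexes in convR the splits could show nothing about chance, because each of 100 and 60 splits gives at least 0. The highest others were 448 and 5. For edgeR, 1940 and 651 genes had an unadjusted p under 0.05 in these tests and DESeq2 called 278 and 4.

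Chance was unlikely to have made the remaining counts, all above 0. For each of them the labelled split alone, 1 of 50 or 100, gave as many, which is the smallest share these splits could give. For GF females the real count was 2417 and the highest other 380, for GF males 4091 and 1049, for the sexes in convR 9058 and 18 and for the sexes in GF 7589 and 1948. For rhythmic genes they were 1967 and 102 in convR females, 2041 and 56 in GF females, 1540 and 411 in convR males and 2955 and 744 in GF males.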

How the results depend on the processing

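The comparisons, the named-gene rule, the lists and the other alternatives were chosen before the data were examined. The settings that leave out libraries with high Nnt, with pancreas or muscle counts, with high Mir5105, or all 7 of these, or pseudogene and small RNA genes, were chosen only after the result was seen. The median clock amplitude difference in females, which carried no test, ran from -0.09 to 0.26, so its sign was not stable. No tested value reversed, and no named gene called at first reversed its direction under any alternative. Of the combinations of result and alternative, 733 were labelled as the same and 143 as moved. A count was labelled as the same when it stayed within a set tolerance of the first value, so the same does not mean unchanged. The interaction count, 1443 at first, ran from 1005 to 1987 with single libraries left out, and 0 libraries were labelled as moving it. The cause of the moves was not tested except where fewer libraries, fewer ZT or a stricter threshold were the alternative itself.

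At an adjusted p of 0.01 the counts were 910 in GF females, 2459 in GF males and 477 for the interaction. Rhythmic genes then numbered 697 in convR females, 773 in GF females, 498 in convR males and 1346 in GF males, 3 changed in males, and 8 differed between the sexes in GF.

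With library size as the only scaling 4082 genes changed in GF females. DESeq2 gave 2319 rhythmic genes in convR males, 278 changed in females, 300 changed in males, and 4 and 147 differing between the sexes in convR and GF. With no filter these were 2730, 215, 1014, 425 and 883. The 5 df test of ZT gave 3496, 71, 295, 36 and 285.

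Without ZT2 the count was 1476 in GF females, 1210 and 2754 rhythmic in convR females and males, 5 and 194 changed in females and males, and 21 and 130 differing between the sexes in convR and GF. Without ZT6, 14 changed in males and 2 differed in GF. Without ZT10 the counts were 1374 in GF females, 603 for the interaction, 898 and 377 rhythmic in convR females and males, 1522 in GF males, and 3 and 2 changed. Without ZT14 they were 1194, 939, 453 and 1460 rhythmic in convR females, GF females, convR males and GF males, 3 and 5 changed, and 11 differing in GF. Without ZT18 they were 791 for the interaction, 931 and 1864 rhythmic in convR and GF males, 62 and 0 changed, and 1 differing in convR. Without ZT22 they were 1513 in GF females, 966, 1137 and 2601 rhythmic in convR females, GF females and convR males, 44 changed in males and 21 differing in GF.

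Without the 3 libraries with pancreas or muscle counts the interaction count was 778, with 599 rhythmic in convR males, 4 changed in males, and 1 and 25 differing between the sexes in convR and GF. Without the high Mir5105 library 2410 were rhythmic in convR males, and 1 and 21 differed. Without the 3 high Nnt libraries 3 differed in GF, and the loss of the sex difference was -0.145 (exact p = 0.25, at 3 ZT). Without all 7, 1272 and 1006 were rhythmic in GF females and convR males, 4 changed in males, and 1 and 0 differed.

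Without either replicate number each cell held 1 library, assumed to vary like the others, and counts ran from 209 to 281 in GF females, 709 to 867 in GF males, 56 to 119 for the interaction, 4522 to 4747 and 3704 to 3939 for the sexes in convR and GF. Rhythmic genes ran from 14 to 245 in convR females, 91 to 424 in GF females, 12 to 32 in convR males and 129 to 160 in GF males. Changed rhythms ran from 0 to 35 in females and 0 to 0 in males, and 2 to 4 differed between the sexes in GF. Without replicate numbers 1 and 2 the clock peak shift in females was 2.44 and 1.84 h. Leaving out any 1 library gave at most 2776 genes in GF females, 5168 in GF males, 1987 for the interaction, 9688 and 8324 for the sexes in convR and GF, and 2332, 2189 and 3055 rhythmic in convR females, GF females and GF males.

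Single libraries moved rhythm counts. In convR females leaving out ZT10 replicate 2 or ZT14 replicate 2 gave 1214 and 1288, and in convR males ZT10 replicate 1, ZT14 replicate 1 and ZT10 replicate 2 gave 1019, 878 and 890. Changed rhythms in females numbered 1 and 1 without convR ZT6 replicates 1 and 2, and 25, 227, 4, 3, 20 and 2 without GF ZT2 and ZT18 replicate 1 and ZT2, ZT14, ZT18 and ZT22 replicate 2. In males they numbered 13, 10, 11, 14, 8 and 11 without convR ZT18 and ZT22 replicate 1 and ZT6, ZT10, ZT18 and ZT22 replicate 2, and 13, 5 and 35 without GF ZT18 replicates 1 and 2 and ZT22 replicate 2. Between the sexes in convR they numbered 1, 1, 2 and 1 without male convR ZT10 and ZT18 replicate 1, ZT2 replicate 2 and GF ZT6 replicate 2. In GF they numbered 37, 33, 21, 36 and 32 without male ZT6 and ZT18 replicate 1 and ZT6, ZT14 and ZT18 replicate 2, and 30, 15, 34 and 132 without female ZT6 replicate 1 and ZT6, ZT10 and ZT18 replicate 2.

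With an estimated correlation 0, 4, 4, 3 and 4 lists passed for GF females, GF males, the interaction and the sexes in convR and GF, and fry passed 24 for the sexes in convR. With replicate number 2 choosing the genes the female slope was -0.058 (exact p = 0.0312, n = 6).

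Replicate numbers were not taken to pair the samples, as correlations of equal numbers ran from -0.217 to 0.18 in females and -0.066 to 0.302 in males and exceeded 0.1 at 3 and 2 of 6 ZT. 0 genes in females and 120 in males differed between the numbers. A replicate block gave 2361 genes in GF females, 4223 in GF males, 1449 for the interaction, 7182 and 6171 for the sexes in convR and GF, 18 changed in males and 55 differing between the sexes in GF. Depth was not varied for the rhythm tests. The simulation planted rhythms in GF on genes without any. At the measured depth and number of samples, 2-fold rhythms were found for 61.2% of genes in females and 53.7% in males.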

Other observations

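SLC25A37 in females and Fgfbp3 in both sexes, genes chosen after their values were seen, also differed between convR and GF livers. SLC25A37 (ENSMUSG00000093954), a gene model named for a mitochondrial iron carrier, held 318 counts over convR females and 0 over GF females, at least 103-fold lower in GF. Slc25a37 (ENSMUSG00000034248) is a separate entry with an average log2 CPM of 4.68 in females, and its mean GF effect is not given here. Fgfbp3, a growth factor binding protein gene near Ide on chromosome 19 (36917550 to 36919615), stood in GF at 0.389 of its convR level in females and 0.509 in males.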
